A study of Homo sapiens with 4 samples.

How the data were processed

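RNA was sequenced from H1299 cells, with 2 libraries per group and 4 in all. Per the labels, cells received 0.5 mM methylparaben or ethanol, and methylparaben exposure lasted 48 h. Total RNA was extracted with Trizol, mRNA was pulled down with poly(A) beads, and libraries were made with an Illumina TruSeq kit. The authors deposited raw read counts per annotated transcript, with no normalisation, for 206601 transcripts of 58735 genes. The counting program and the aligner are not given in the sources used here, and the submitters' notes list the build GRCh38 and the tools DESeq2, limma and edgeR without versions or roles. The deposited FPKM values follow from the same counts, the listed transcript lengths and a library size that was 1.02, 1.04, 1.01 and 0.985 times the count total in ethanol 1, ethanol 2, methylparaben 1 and methylparaben 2. Per the file headers, further columns hold log2 of the FPKM value plus 1, which was checked on the values. The authors' table also gives a p-value and an adjusted p-value per transcript of their own comparison, without a fold change or the name of the test. These p-values were used only to count overlapping calls.

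All 206601 transcripts were found in GENCODE release 29 at the same coordinates, and positions are given on GRCh38 counted from 1. Bases that belong to a single annotated transcript were derived from the exons. None of the 70749 transcripts without such a base had a read, and none of the 3138 transcripts with such a base only when strands are kept apart had one, so reads were counted on single-transcript bases regardless of strand. Transcripts with at least 500 such bases numbered 37580, of which 50.9% had reads, and held 92.3% of all reads. Of 19951 protein-coding genes, 11773 had under 50% of their exonic bases in a single transcript and 375 had none, so the counts of such genes come from part of their RNA. Antisense, pseudogene and overlapping features were read without strand and are uncertain. A total of 166322 transcripts had 0 counts in all libraries.

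Counts of the transcripts of each Ensembl gene were summed, since the deposited table holds transcripts and not the gene counts that had been planned for. Genes were filtered with filterByExpr at its defaults (minimum count 10, minimum total 15), scaled by the trimmed mean of M values (TMM) and compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 8055 genes and a threshold of 0.05. The SE of a log2 fold change is its size over the square root of F. CPM are TMM-scaled. Gene lists with at least 5 tested members, 28 of 40 fixed before the data were examined, were tested with camera of limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. Adjustment was over the 28 lists. Of the 40 lists 35 were pathways or gene families and 5 were markers of cell types. Members were also counted adjusted over the list alone.

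The lists were DNA replication, G2/M and mitosis, homologous recombination and DNA repair, replication-dependent histones, ATF4 and ER stress, heat shock proteins, NRF2, AhR targets, phase II and ester hydrolysis enzymes, estrogen-responsive genes, PPAR targets, cholesterol biosynthesis, fatty acid and lipid synthesis, glycolysis, hypoxia, nuclear-encoded respiratory chain, mitochondrially encoded transcripts, interferon-stimulated genes, NF-kB and inflammatory genes, immediate early genes, TGF-beta and extracellular matrix, mesenchymal markers, epithelial markers, YAP and TEAD targets, Wnt and Notch targets, metallothioneins and zinc transport, pro-apoptotic and anti-apoptotic genes, histone-modifying enzymes, DNA methylation enzymes, telomerase and shelterin, autophagy and lysosome, cytosolic ribosomal proteins, and MYC and ribosome biogenesis. Cell type lists covered lung, neuroendocrine, blood and immune, hepatocyte, and breast luminal and urogenital markers.

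Genes to name were fixed by rule before the data were examined. They were the 12 largest increases and 12 largest decreases among called genes with a symbol, not pseudogenes, at a mean of 5 CPM or more, up to 4 called members of each pathway list by smallest p, a set of check genes, and the 5 most abundant genes. Some of these genes and 1 list are not reported here. A fold against a group with 0 counts is a bound computed with 3 counts over the group, and with 1 to 3 counts the ratio has its exact binomial 95% interval. Such limits and intervals cover counting error only. Library totals ran from 2068486 to 3760982 counts. Alternatives were other scalings (RLE, upper quartile, library size only), DESeq2 1.42.0, limma voom, no or a stricter filter (5 CPM in 2 libraries), the replicate number as a block, limma on log2 FPKM with pseudocounts of 1 and 0.1, and leaving out each library. Where a library is left out, the lone library of its group is assumed to vary like the other group. Alternatives chosen after seeing the data were transcripts in place of genes, retained-intron transcripts left out, only genes with at least 50% single-transcript bases, the mitochondrial genome left out, an offset for GC content and length, and a crossed block. With 2 libraries per group, tests for outlying libraries and for other splits of the samples were not used here.

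The pipeline was tested on simulated negative binomial counts for 8055 genes with 2 libraries per group. edgeR recovered 24.8% of 2-fold and 70.2% of 4-fold changes, with 4.81% of calls false, and camera called the shifted list in 20 of 20 runs and 1 of 540 unshifted lists. For edgeR 100 genes were changed at each size, far fewer than were called in the data. Genes were simulated independently, so the list rates hold only without correlation between genes. Further software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and the R package for data tables at 1.17.8, and plots were drawn with matplotlib 3.10.9.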

Results

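RNA-seq libraries were made from H1299 cells, a human non-small-cell lung carcinoma line. Cells exposed to 0.5 mM methylparaben, a phenolic ester used as a preservative, for 48 h gave 2 libraries, and ethanol control cells gave the other 2. The comparison asks which transcripts differ between the treated and the control cells. Total counts were 2368658 and 2182058 in ethanol replicates 1 and 2 and 3760982 and 2068486 in methylparaben replicates 1 and 2. A library in which no read was counted for a gene allows a level of up to 1.27, 1.37, 0.798 and 1.45 CPM (read counts scaled to the library total) in that order, taking 3 counts as the limit, and such limits cover counting error only. The design text says that experiments were duplicated but not that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Log2 CPM correlated across genes, which are not independent replicates, at 0.963 between the ethanol libraries and 0.957 between the methylparaben libraries, and at 0.816 to 0.853 between groups. Within each group the counts differed by more than sampling noise, with chi-square per degree of freedom of 7.89 for ethanol and 22 for methylparaben.

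The deposited counts hold reads only where a base belongs to a single annotated transcript, and some check genes were scarcely read. GAPDH, a glycolytic enzyme often used as a reference gene, had 0, 1, 0 and 1 counts in ethanol 1, ethanol 2, methylparaben 1 and methylparaben 2, although 46.2% of its exonic bases lie in a single transcript, and the cause was not tested. CDKN1A, a cyclin-dependent kinase inhibitor gene, had 0, 1, 1 and 0 counts, and CYP1A1, a classical aryl hydrocarbon receptor target, had 1, 0, 0 and 0. ESR1, which encodes estrogen receptor alpha, had 21, 16, 1 and 0 counts. Its ratio of methylparaben over ethanol was 0.0226 (95% interval 0.000556 to 0.134), with an adjusted p of 0.00233 that became 0.0654 without ethanol replicate 1.

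In methylparaben-treated H1299 cells, 14 of 21 tested ATF4 and endoplasmic reticulum (ER) stress genes and 10 of 13 cholesterol synthesis genes were higher, and 1 of these ER stress genes was lower. Of the genes tested, 8 of 13 for DNA replication, 10 of 11 for mitosis, 12 of 13 encoded in mitochondria and 8 of 12 YAP targets were lower. The lists held 28 ATF4 and ER stress, 24 cholesterol, 36 replication, 32 mitosis, 13 mitochondrial and 24 YAP genes. Members not tested had too few counts. The camera list test called these 6 lists at a preset correlation between genes and none of them at an estimated one (adjusted p = 0.553 for each). HSPA5, the ER chaperone BiP, rose 14-fold, from 3669.6 ± 208 to 51202 ± 4449 CPM (SD, n = 2 per group), and took 4.70% and 5.02% of all counts in the methylparaben libraries against 0.379% and 0.373% in the ethanol libraries. HMGCS1, which makes HMG-CoA for sterol synthesis, rose 23.6-fold, from 5.36 ± 0.370 to 127 ± 28.4 CPM, with 100% of its reads on retained-intron transcripts, and none on a protein-coding transcript. CTGF, a matricellular protein gene and YAP target, fell 10.2-fold, from 1457 ± 130.4 to 142 ± 4.11 CPM, and BIRC3, an inhibitor of apoptosis, fell 17.2-fold, from 309 ± 0.105 to 17.9 ± 0.116 CPM. CCND1, which encodes cyclin D1, fell 5.67-fold, from 688 ± 21.2 to 121 ± 2.03 CPM.

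Among 8055 genes tested with edgeR's quasi-likelihood test, 2976 had a Benjamini-Hochberg adjusted p under 0.05, of which 1491 were higher and 1485 lower with methylparaben. Of these, 2359 differed by at least 2-fold, 1201 higher and 1158 lower. Of 391 tested members of the gene lists fixed in advance, 193 changed, and 6 of 28 lists with at least 5 tested members were called by the camera list test. With an estimated correlation camera called 0 lists, 1 list, cholesterol biosynthesis, having an unadjusted p under 0.05 (0.0433), while the fry test called 15. Without ethanol replicate 1 the counts were 1677 genes, 1560 genes at 2-fold and 121 list members. On the deposited FPKM values, limma called 55 to 1063 genes depending on the pseudocount and the filter. Adjusted p values below are from the edgeR test unless a list test is named, ± marks the SE of a log2 fold change or the SD of a CPM, and n is 2 per group throughout. All calls rest on genes with reads outside the bases shared between transcripts.

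**Figure D1:**
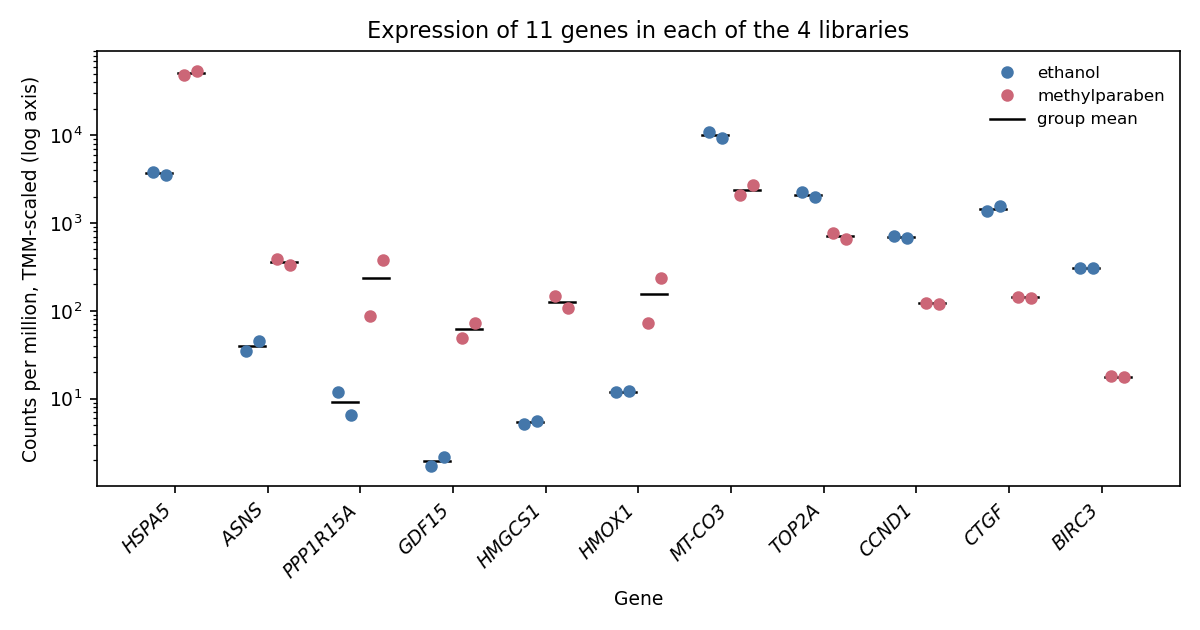
TMM-scaled CPM on a log axis for 11 named genes, with a point for each of the 2 ethanol (blue) and 2 methylparaben (red) libraries and a black line at each group mean. HSPA5 reached 48056 and 54348 CPM in the methylparaben libraries, while PPP1R15A differed between them, at 86.3 and 381 CPM.

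The ATF4 and ER stress list had 14 of 21 tested members higher and 1 lower over all genes tested, and 15 higher and 1 lower adjusted over the list alone. Its median log2 fold change was 1.62, and camera called it higher (adjusted p = 8.04e-05, and adjusted p = 0.553 with an estimated correlation). The examples with the smallest p were HSPA5 (chromosome 9, 125234853 to 125241330, GRCh38), with an adjusted p of 1.43e-05, ASNS, asparagine synthetase, at 3.18 ± 0.21 with 2.74e-05, ERN1, the ER stress sensor IRE1, at 2.14 ± 0.18 with 7.54e-05, and HERPUD1, a component of ER-associated degradation, at 2.15 ± 0.23 with 0.000230. Retained-intron transcripts held 64.7% of the ASNS and 70.7% of the HERPUD1 reads, against 0.441% for ERN1 and 0 for HSPA5. With such transcripts left out, 12 of 16 tested members rose and 1 fell. PPP1R15A, which directs dephosphorylation of eIF2-alpha, rose by 4.64 ± 0.66, from 9.20 ± 3.83 to 234 ± 208 CPM. The member that fell was VLDLR, a lipoprotein receptor gene, at -1.72 ± 0.34. XBP1, a transcription factor gene of the unfolded protein response, was at 0.71 ± 0.26 with an adjusted p of 0.0552 and 98.8% of its reads on retained-intron transcripts, and PSAT1, a serine synthesis enzyme, was at -0.35 ± 0.18 with 0.144, and these 3 genes were singled out after their values were seen. In the heat shock protein list 8 of 14 tested members rose and 4 fell, among them HSPA1B at 2.20 ± 0.24, CHORDC1 at 1.78 ± 0.22, DNAJA1 at -1.61 ± 0.17 and HSPA4 at -2.50 ± 0.26, and camera did not call the list (adjusted p = 0.155). The counts for heat shock proteins were the same adjusted over the list alone, and were 4 higher and 4 lower of 9 without retained-intron transcripts.

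In the cholesterol biosynthesis list, 10 of 13 tested members rose and 0 fell, with the same counts adjusted over the list alone. The median log2 fold change was 1.61, and camera called the list higher (adjusted p = 8.04e-05, and adjusted p = 0.553 with an estimated correlation). HMGCS1, read only on retained-intron transcripts, rose by 4.56 ± 0.31 with an adjusted p of 3.01e-05, and MSMO1, a sterol demethylation enzyme read mainly on a protein-coding transcript, by 3.33 ± 0.49 with 0.000958. FDFT1, which encodes squalene synthase, had 2 and 57 counts in the ethanol and methylparaben groups, a ratio of 23.8 (95% interval 6.29 to 201), and INSIG1, which retains the SREBP complex in the ER, had 2 and 55 counts, a ratio of 22.9 (95% interval 6.06 to 194). Retained-intron transcripts held 15.3% of the FDFT1 and 100% of the INSIG1 reads. Without retained-intron transcripts 6 of 9 tested members rose, and without ethanol replicate 1, 6 of 14 rose. Of 9 tested genes of fatty acid and lipid synthesis, 3 rose and 1 fell, including ACSS2, which makes acetyl-CoA from acetate, at 2.19 ± 0.26 with 98.9% of its reads on retained-intron transcripts, and ELOVL6, a fatty acid elongase, at -1.87 ± 0.21. Of 8 tested PPAR target genes, 3 rose and 0 fell over all genes, against 3 and 1 adjusted over the list alone. Without retained-intron transcripts, 1 of 7 lipid synthesis genes rose and 1 fell, and 0 of 5 PPAR targets passed. With ethanol replicate 1 left out, 2 of 9 lipid synthesis and 0 of 8 PPAR target genes passed, and 1 PPAR target did without ethanol replicate 2 or without methylparaben replicate 1.

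Most tested cell cycle genes were lower. Only 13 of 36 listed DNA replication genes and 11 of 32 listed G2/M and mitosis genes could be tested. In the DNA replication list 8 of 13 tested members fell and 0 rose, and 11 fell adjusted over the list alone. In the G2/M and mitosis list 10 of 11 fell by either count, the remaining tested member being PTTG1 at 0.67 ± 0.52 with an adjusted p of 0.339. PTTG1 and BUB1, named after their values were seen, and CDK1 were read mainly on retained-intron transcripts, and without such transcripts 7 of 10 replication and 8 of 9 mitosis genes fell and 0 rose. Median log2 fold changes were -1.78 and -1.57, and camera called both lists lower, with adjusted p = 8.04e-05 for replication and 0.000553 for mitosis, and adjusted p = 0.553 with an estimated correlation for each. The flap endonuclease gene FEN1 was at -1.78 ± 0.24 and the clamp loader gene RFC3 at -1.25 ± 0.19, and GINS1 of the replicative helicase went from 56.2 ± 4.95 to 13.0 ± 1.30 CPM. TOP2A, encoding topoisomerase II alpha, went from 2098 ± 206 to 708 ± 75.2 CPM, the mitotic kinesin gene KIF11 from 1279.7 ± 25.9 to 381 ± 64.7 CPM, CENPF from 1668 ± 379 to 496 ± 44.6 CPM and CDK1, with 98.8% of its reads on retained-intron transcripts, from 121 ± 14.6 to 29.6 ± 4.09 CPM, with adjusted p between 0.000166 and 0.000317. Without ethanol replicate 1, 5 of 14 tested replication genes fell, and without methylparaben replicate 1, 8 fell and 1 rose. Of 10 tested homologous recombination and DNA repair genes 1 rose and 2 fell by both counts, namely ATM at 2.02 ± 0.31, BRIP1 at -1.84 ± 0.23 and XRCC2 at -1.65 ± 0.30, with 99.7% of the XRCC2 reads on a noncoding processed transcript. Among 4 tested replication-dependent histone genes, 2 rose and 1 fell by both counts, with HIST2H2BE at 1.15 ± 0.18 and HIST1H2BC at -1.27 ± 0.28.

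Of the 13 mitochondrially encoded mRNAs, 12 fell, and 13 fell adjusted over the list alone. Their median log2 fold change was -1.32, and camera called the list lower (adjusted p = 8.04e-05, and adjusted p = 0.553 with an estimated correlation). MT-ATP6 went from 8206 ± 1378 to 1759 ± 128 CPM, MT-CO3 from 10139 ± 1135 to 2382 ± 413 CPM, MT-ND2 from 12055 ± 1292 to 3227 ± 317 CPM and MT-ATP8 from 1418 ± 308 to 210.1 ± 95.8 CPM, with adjusted p between 8.86e-05 and 0.000224. These genes encode subunits of ATP synthase, cytochrome c oxidase and complex I. The 13 mRNAs together held 18.8% and 16.4% of the counts in the ethanol libraries and 7.28% and 8.61% in the methylparaben libraries, whereas the mitochondrial rRNAs held 4.71% and 4.12% against 10.5% and 9.75%. MT-RNR2, the large mitochondrial rRNA, rose by 1.27 ± 0.22, from 40241 ± 5472 to 97247 ± 3946 CPM, with an adjusted p of 0.00208. MT-CO1 and MT-ND4, the other mitochondrial genes among the 5 most abundant features, were at -0.78 ± 0.23 and -0.85 ± 0.21 with adjusted p of 0.0254 and 0.0103, which became 0.188 and 0.122 without ethanol replicate 1, and MT-CO1 was at 0.0676 without ethanol replicate 2. Of 26 tested nuclear-encoded respiratory chain genes 7 rose and 3 fell by both counts, against 2 and 3 of 31 without ethanol replicate 1, including ATP5F1B at 1.59 ± 0.30, read only on noncoding processed transcripts, and UQCRB at -1.80 ± 0.29, and camera did not call that list (adjusted p = 0.396). EEF1A1P5, a processed pseudogene that shares sequence with the elongation factor gene EEF1A1, was also among the 5 most abundant features, at 0.62 ± 0.31 with an adjusted p of 0.139 that became 1.20e-07 without methylparaben replicate 1, and its reads cannot be assigned to the pseudogene with certainty.

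Most tested targets of the YAP and TEAD transcription factors were lower, with 8 of 12 tested members past the threshold and 0 higher, and 9 lower adjusted over the list alone. The median log2 fold change was -1.31, and camera called the list lower (adjusted p = 0.000238, and adjusted p = 0.553 with an estimated correlation). CTGF (chromosome 6, 131948176 to 131951373) was at -3.36 ± 0.18 with an adjusted p of 8.60e-06. CYR61, a related matricellular gene, was at -1.66 ± 0.18, AXL, a receptor tyrosine kinase gene, at -1.41 ± 0.20, and RBMS3 at -2.88 ± 0.36. In the TGF-beta and extracellular matrix list, which shares CTGF, 7 of 13 tested members fell and 2 rose by both counts, among them SPARC at -2.91 ± 0.42 and THBS1 at -2.11 ± 0.32, and camera did not call it (adjusted p = 0.0933). Of 4 tested mesenchymal markers 2 fell by both counts, AXL and VIM, the latter at -1.19 ± 0.25 with an adjusted p of 0.00565 that became 0.0518 without ethanol replicate 1. VIM had 77.7% of its reads on a transcript annotated for nonsense-mediated decay and 0 on protein-coding transcripts. None of 3 tested epithelial markers changed by edgeR, DESeq2 or limma voom, and 0 had an unadjusted p under 0.05.

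**Figure D2:**
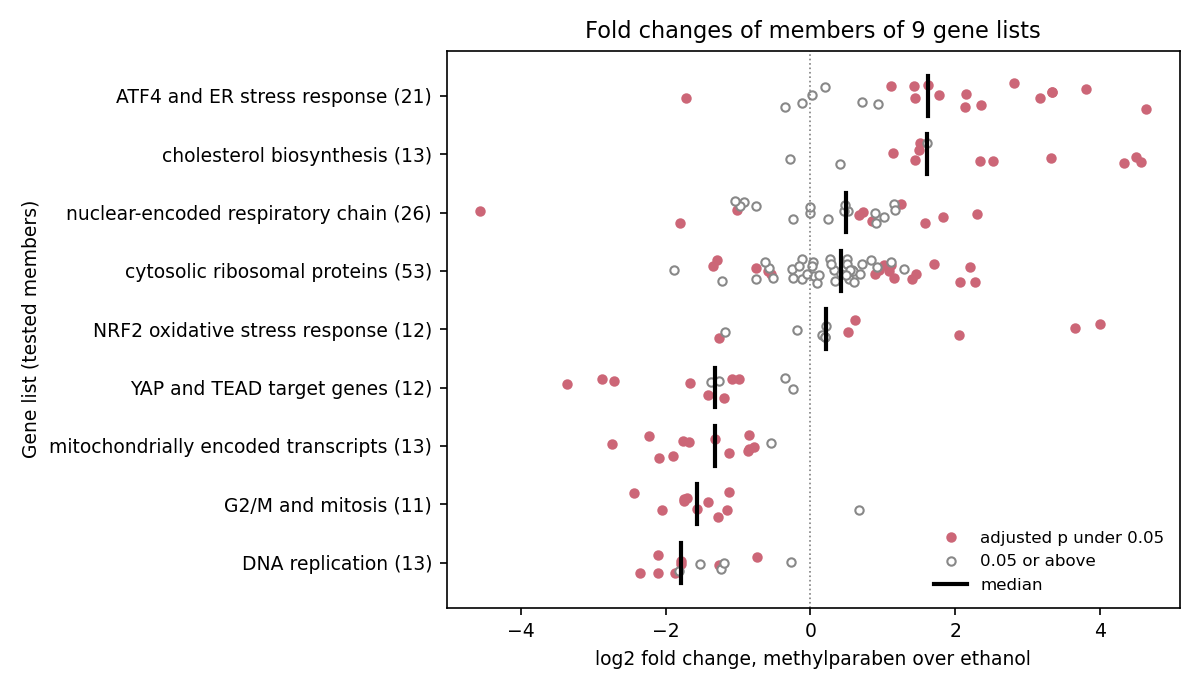
Log2 fold change of methylparaben over ethanol (x axis) for the tested members of 9 gene lists (rows, with the number tested), filled red where the adjusted p is under 0.05 and open otherwise, with a black bar at each median. Medians run from -1.78 for DNA replication to 1.62 for ATF4 and ER stress, and the NRF2, ribosomal protein and respiratory chain lists, which camera did not call, hold members on both sides of 0.

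The NRF2, estrogen-responsive, hypoxia, anti-apoptotic and pro-apoptotic lists were not called by camera, with adjusted p from 0.127 for hypoxia to 0.835 for pro-apoptotic genes, and the AhR target list, with 2 tested members, was too short for camera. Of 12 tested NRF2 oxidative stress genes 5 rose and 1 fell by both counts. HMOX1, heme oxygenase 1, went from 12 ± 0.149 to 154 ± 116 CPM, and FTL, the ferritin light chain gene, from 50.9 ± 2.76 to 818 ± 888 CPM, so both varied widely between the methylparaben libraries. NFE2L2, which encodes NRF2 and belongs to the AhR target list, was at 1.64 ± 0.35, and CYP1B1, the other tested AhR target, was at -3.85 ± 0.39, with 7.35 and 2.62 CPM in the methylparaben libraries, so that 1 rose and 1 fell. Of 5 tested estrogen-responsive genes 1 rose and 3 fell, against 2 and 3 adjusted over the list alone, with CCND1 (chromosome 11, 69641087 to 69654474) at -2.50 ± 0.17, the transcription factor gene MYBL1 at -1.75 ± 0.17, BCL2 at -1.56 ± 0.33 and SIAH2 at 0.92 ± 0.18. In the hypoxia list 4 of 15 rose and 1 fell by both counts. DDIT4, an mTOR inhibitor gene, was at 2.35 ± 0.42 with 6.80 and 18.2 CPM in the ethanol libraries, and EGLN1, an oxygen sensor gene, at -1.17 ± 0.18. Among the others that rose, NDRG1 and VEGFA had 97.2% and 100% of their reads on retained-intron transcripts. Of 6 tested anti-apoptotic genes 2 rose and 3 fell by both counts, BIRC3 (chromosome 11, 102317450 to 102339403) at -4.11 ± 0.20 and CFLAR at -1.90 ± 0.18, and of 5 pro-apoptotic genes 1 fell by both counts, CASP8 at -2.40 ± 0.54 with 7.62 and 1.57 CPM in the methylparaben libraries and 93.7% of its reads on noncoding processed transcripts. Without ethanol replicate 1, 3 NRF2 and 3 anti-apoptotic genes passed. Without ethanol replicate 2, 3 NRF2 and 3 anti-apoptotic genes passed, and without methylparaben replicate 2, 2 of 6 pro-apoptotic genes rose and 1 fell.

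The remaining lists were not called by camera or had fewer than 5 tested members. Immediate early genes had 5 higher and 7 lower of 17, and 5 and 8 adjusted over the list alone, with ATF3 at 3.34 ± 0.39, with 74.2% of its reads on retained-intron transcripts, and EGR1 at -1.93 ± 0.23. Interferon-stimulated genes had 3 higher and 5 lower of 11, and 4 and 6 adjusted over the list alone, with OAS3 at -2.08 ± 0.35 and HERC5 at 2.08 ± 0.37. IFI44L had 25 and 0 counts in the ethanol and methylparaben groups and was at least 9.99-fold lower, with 3 counts over the group as the limit, a bound that was 3.42 without methylparaben replicate 1. Histone-modifying enzymes had 10 higher and 5 lower of 39, and 10 and 6 adjusted over the list alone, among them the acetyltransferase gene KAT2B at -2.48 ± 0.21 and the demethylase gene KDM6B at 2.22 ± 0.39. Cytosolic ribosomal protein genes had 12 higher and 5 lower of 53, including RPL37 at 1.09 ± 0.16 and RPL14 at -1.29 ± 0.24, and 4 higher and 5 lower of 31 without retained-intron transcripts. The MYC and ribosome biogenesis list had 2 higher and 5 lower of 14, with NPM1 at -1.02 ± 0.19 and WDR12 at -1.12 ± 0.23, and its mean was 0.22 although its median was -0.08 and camera's direction was lower. DNA methylation enzymes had 0 higher and 2 lower of 9, TET3 being at -0.93 ± 0.19. Of the telomerase and shelterin list 2 of 5 rose, of autophagy and lysosome genes 2 of 11 rose, SQSTM1 by 3.08 ± 0.42, and of 5 glycolysis genes 1 fell. DKC1 of the telomerase list and NEU1 of the autophagy list, both higher, had 93.6% and 100% of their reads on retained-intron transcripts. NF-kB and inflammatory genes had 1 higher and 1 lower of 7, and metallothionein and zinc transport genes 1 higher of 3. For ribosomal protein, MYC, DNA methylation, telomerase, autophagy, glycolysis, NF-kB, metallothionein, fatty acid and AhR lists the counts adjusted over the list alone were the same. None of 3 tested Wnt and Notch targets and none of 3 tested phase II and ester hydrolysis enzymes passed in edgeR, DESeq2 or limma voom, and 1 and 0 had an unadjusted p under 0.05 in edgeR. Without ethanol replicate 1 the called members numbered 7 immediate early, 3 interferon-stimulated, 9 histone-modifying, 9 ribosomal protein, 2 MYC, 1 DNA methylation, 0 telomerase, 1 autophagy, 0 glycolysis, 1 NF-kB and 0 metallothionein genes. Without ethanol replicate 2 they numbered 0 glycolysis and 0 metallothionein genes, without methylparaben replicate 1, 0 glycolysis genes, and without methylparaben replicate 2, 1 autophagy, 2 glycolysis and 1 Wnt and Notch genes.

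The 12 largest increases and the 12 largest decreases were taken among called genes with a symbol and a mean of at least 5 CPM. NGFR, the p75 neurotrophin receptor gene (chromosome 17, 49495293 to 49515017), had 0 counts in both ethanol libraries and 50 and 102 in the methylparaben libraries, with an adjusted p of 0.00130. The latter are 13.6 and 53.4 CPM, so they differ widely. NGFR was at least 42.3-fold higher with 3 counts over the group as the limit, a bound that was 21.1 without methylparaben replicate 2 and 83.0 without replicate 1. TMEM41B, a gene for an ER lipid scramblase, and GTF3C1, a subunit of transcription factor TFIIIC, were at least 22-fold and 15.6-fold higher by the same limit (10.9 and 7.72 without ethanol replicate 1), with 100% and 96.4% of their reads on retained-intron transcripts. DCT, which encodes the melanin synthesis enzyme dopachrome tautomerase, had 1 and 139 counts in the groups, a ratio of 116 (95% interval 20.5 to 4614). Ratios were 30.5 (95% interval 8.14 to 256) for CLASP1, 29.6 (95% interval 7.91 to 249) for GPR107 and 26.7 (95% interval 8.87 to 132) for the clock gene PER3, and 61.3% of the CLASP1 reads and 98.0% of the PER3 reads lay on retained-intron transcripts and 95.9% of the GPR107 reads on transcripts annotated for nonsense-mediated decay. SARAF, a regulator of store-operated calcium entry, rose by 4.44 ± 0.54. GDF15, a secreted stress-induced cytokine gene, rose by 4.95 ± 0.42, from 1.93 ± 0.327 to 61.4 ± 16.8 CPM. The other increases of this set were PPP1R15A, HMGCS1 and FDFT1. Adjusted p values of the 12 ran from 3.01e-05 to 0.00366.

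Among the decreases, TM4SF18, encoding a tetraspan membrane protein, went from 92.4 ± 4.61 to 1.60 ± 0.0442 CPM and SERTAD4 from 71.1 ± 12.1 to 2.16 ± 1.57 CPM. The antisense transcript SGMS1-AS1, read without regard to strand, was at -4.89 ± 0.44, and the long noncoding RNA LINC00857 at -5.13 ± 0.54. For the other 8 the methylparaben libraries held 1 to 3 counts in all. Ratios of methylparaben over ethanol were 0.00927 (95% interval 0.000232 to 0.0530) for IL7R, the interleukin 7 receptor, and 0.00927 (95% interval 0.000232 to 0.0530) for RAET1E, a ligand of the NKG2D receptor, each with 90 and 1 counts in the ethanol and methylparaben groups. They were 0.0149 (95% interval 0.000371 to 0.0865) for SH3TC2, with 52.6% of its reads on transcripts annotated for nonsense-mediated decay, 0.0178 (95% interval 0.00212 to 0.0659) for KLHL14, 0.0205 (95% interval 0.00417 to 0.0614) for CDK15 and 0.0216 (95% interval 0.00439 to 0.0647) for LINC02535. ARL14, a small GTPase gene, was at 0.0303 (95% interval 0.00359 to 0.115), and NDUFB5, a complex I subunit gene with 59.6% of its reads on a retained-intron transcript, at 0.0371 (95% interval 0.00436 to 0.142). Adjusted p values of these 12 ran from 1.90e-05 to 0.00303. All 24 genes kept their direction in every alternative that tested them. Only GDF15, HMGCS1 and TM4SF18 kept an adjusted p under 0.05 in each of these alternatives.

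Tested transcript by transcript, as the counts were deposited, 3613 of 9167 transcripts passed the threshold, 1859 higher and 1754 lower. Transcripts annotated as retained introns stood apart, with 613 of 1545 higher, 93 lower and a median log2 fold change of 1.02, whereas protein-coding transcripts had 684 of 4662 higher, 1182 lower and a median of -0.18. Retained-intron transcripts held 2.73% and 2.73% of the counts in the ethanol libraries and 4.22% and 3.95% in the methylparaben libraries. Processed pseudogenes had 182 of 1022 higher and 76 lower. Of 12 tested small nucleolar RNAs 8 rose and 0 fell. The authors' deposited table lists 4471 transcripts with an adjusted p under 0.05, of which 3186 were among the 9167 tested here and 3022 were also called here.

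**Figure D3:**
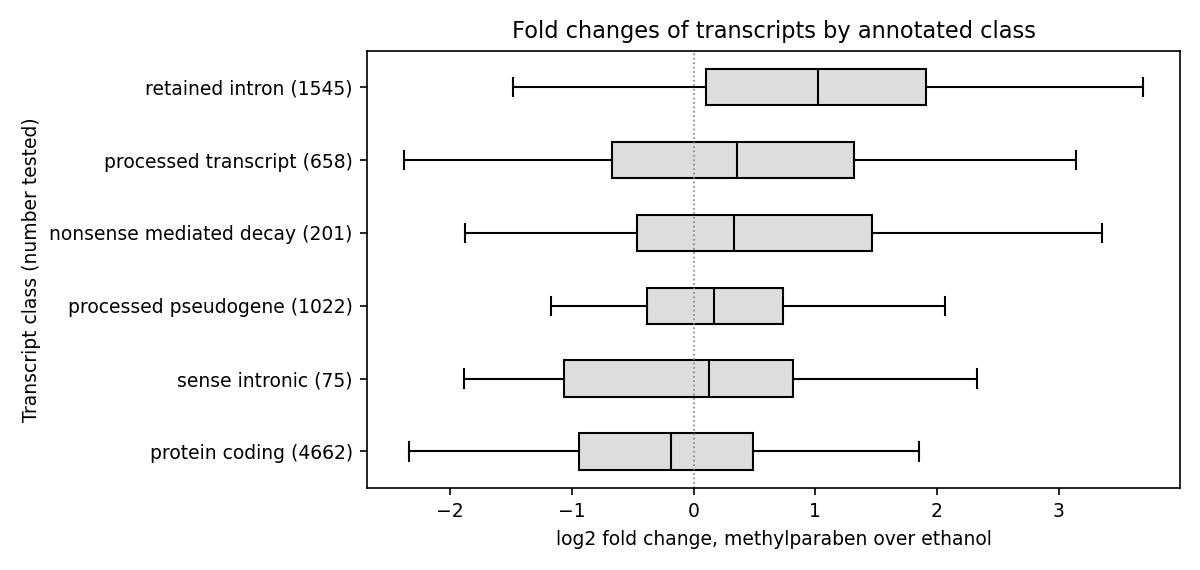
Log2 fold change of methylparaben over ethanol (x axis) by annotated transcript class (rows, with the number tested). Boxes show the quartiles with the median as a black line and whiskers the 5th and 95th percentiles, and the retained-intron median lies at 1.02 against -0.18 for protein-coding transcripts.

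Few cell type markers could be tested. The 18 blood and immune markers had 0 counts in each library, and the 14 hepatocyte markers had 5, 2, 6 and 1 counts in ethanol 1, ethanol 2, methylparaben 1 and methylparaben 2, so no member of either list could be tested. Such low counts do not show that these RNAs were absent, since GAPDH also had 0 or 1 counts in each library. Breast luminal and urogenital markers had 100, 65, 63 and 34 counts, or 42.2, 29.8, 16.8 and 16.4 CPM by library total summed over the list, with 1 of 2 tested members, ESR1, lower, and 0 without ethanol replicate 1 (adjusted p = 0.0654). Lung lineage markers had 38, 50, 32 and 19 counts (16.0, 22.9, 8.51 and 9.19 CPM), with 1 of 2 tested members lower, the stem cell transcription factor gene SOX2 at -3.98 ± 0.66 with an adjusted p of 0.00179. Neuroendocrine markers had 319, 279, 370 and 240 counts (135, 128, 98.4 and 116 CPM), with 1 of 3 tested members lower, the secretogranin gene SCG2 at -2.05 ± 0.32 with an adjusted p of 0.00136, and the list's median was 0.22 although its mean was -0.46. SOX2 and SCG2 were singled out after their values were seen, and the counts of these 3 lists were the same adjusted over the list alone.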

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

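Alternatives chosen after the data were seen were transcripts in place of genes, retained-intron transcripts left out, genes with at least 50% single-transcript bases, the mitochondrial genome left out, the GC and length offset and the crossed block. The 2976 called genes became 2007 to 3196 with other scalings, DESeq2, voom and other filters, and 2077 to 3207 with the alternatives chosen later other than the crossed block. Leaving out 1 library gave 1677 to 3095 genes, 1560 to 2495 genes at 2-fold and 121 to 191 list members, the lowest without ethanol replicate 1. On log2(FPKM + 1) with a mean of 1 or more, limma called 1063 genes, 1030 at 2-fold and 93 list members. With a pseudocount of 0.1 these were 679, 667 and 67, and with no filter 55, 55 and 7, and the cause was not tested. Restricted to genes with at least 50% single-transcript bases, 120 of 240 tested list members passed, as fewer genes were tested. The list test called 6 of 28 lists, 0 with an estimated correlation and 15 with fry, and 4 to 7 under the other alternatives. On the genes with at least 50% single-transcript bases, cholesterol biosynthesis had 2 tested members and was too short for camera. In the same setting G2/M and mitosis, with 6 tested members, had an adjusted p of 0.0660 by camera. Over its alternatives that p ran from 0.000374 to 0.553. The share of calls that were higher was 50.1%, and 44.3% with library size only, where the median of all genes was -0.08 against 0.03.

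Of 2518 comparisons of the 124 named genes with an alternative, 2233 kept direction and side of the threshold, 269 lost their call, 4 gained one and 12 changed direction. None of the genes that changed direction, KRT8, DSP and ZNRF3, was called. KRT8 ran from -0.039 to 0.68 when 1 library was left out, lowest without ethanol replicate 2. DSP ran from -0.26 without ethanol replicate 2 to 1.60, and was -0.0339 without methylparaben replicate 2. ZNRF3 was -0.0914 with library size only, -0.00611 with voom, -0.0247 on log2(FPKM + 1) with or without the filter, -0.0327 with a pseudocount of 0.1, -0.00261 by transcript and -0.20 with the GC and length offset. It ran from -0.0931 without ethanol replicate 1 to 0.15, and was -0.0806 without methylparaben replicate 2. The cause of these changes was not tested. GAPDH, CDKN1A and CYP1A1 had at most 1 count in a library and were not tested.

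The labels share replicate numbers, but same-numbered deviations from the group means correlated at -0.15 across genes, which are not independent replicates. With the replicate block 2488 genes were called, and with the crossed block 3292.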

Other observations

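The tests of ER protein quality control genes, of tRNA synthetases, of sense-intronic transcripts and of the mitochondrial rRNA to mRNA ratio were chosen only after the result was seen, the first list after its members OSTC and UFD1 and the second after RARS had been seen among the largest changes. ER protein quality control genes lie outside the fixed list, and 17 of 40 tested members were higher and 1, the protein disulfide isomerase gene PDIA3, lower (-0.84 ± 0.28). SEL1L, which builds the ER ubiquitin ligase complex, had an adjusted p of 0.000250 for its increase. HSPA13 was at 1.33 ± 0.16, DNAJC3, a co-chaperone of BiP and inhibitor of PERK, at 1.62 ± 0.23, the COPII coat gene SEC24A at 1.26 ± 0.18 and the stress sensor gene ATF6 at 0.74 ± 0.16. The median log2 fold change was 0.73, against -0.31 to 0.39 in 95% of 10000 random lists matched for expression. For lists matched also for transcript class the range was -0.27 to 0.43. Class was retained intron, protein-coding or other, by the most-read transcript of each gene. Without OSTC and UFD1, 15 of 38 were higher and 1 lower, and the median was 0.71, against -0.32 to 0.41 and -0.29 to 0.41 for random lists of these 2 kinds. Genes of the random lists were drawn singly, so these ranges ignore correlation between list members. For the called fixed lists, camera with an estimated correlation gave an adjusted p of 0.553. The 27 members whose most-read transcript was protein-coding had a median of 0.52, with 10 higher and 1 lower. With ethanol replicate 1 left out, 9 members were higher and 0 lower. A hypothesis is that ER protein folding, degradation and export genes may have risen as a wider group than the fixed list holds, which further cultures tested on this list as it stands would decide.

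Of 15 tested cytosolic aminoacyl-tRNA synthetase genes, 9 were higher and 1, FARSB, lower (-0.58 ± 0.16). RARS was at 3.84 ± 0.24 and GARS at 3.60 ± 0.48, each with a retained-intron transcript as its most read, and AARS, with a protein-coding one, at 1.61 ± 0.29. The median was 1.38, against -0.52 to 0.59 in 95% of 10000 random lists matched for expression. For lists matched also for transcript class the range was -0.32 to 0.81. IARS, TARS, YARS and SARS, with a processed transcript as the most read, fell in the class of other transcripts. That class pools types of unlike medians, such as 0.35 for processed transcripts and -0.48 for long intergenic noncoding RNAs, so the match is incomplete for these genes. Without RARS the median of the synthetases was 1.35, against -0.52 to 0.63 and -0.36 to 0.79 for random lists of these 2 kinds. These ranges too ignore correlation between list members. The 6 genes whose most-read transcript was protein-coding had a median of -0.15, with 1 higher and 1 lower, so a rise of the coding mRNAs stays open. With ethanol replicate 1 left out, 6 genes were higher and 0 lower.

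Retained-intron transcripts were higher with methylparaben, 613 against 93 lower. The trend of protein-coding transcripts on transcript GC content and length does not account for all of it. After that trend was removed, the median difference from protein-coding transcripts was 1.02 (95% interval 0.93 to 1.10). Reads were counted on single-transcript bases only. The GC content and length of those bases were not tested, so this result cannot exclude them as a cause. The 75 sense-intronic transcripts had a median of 0.13 (-0.32 to 0.50), so this class did not rise as the retained introns did. They are annotated separately and do not measure the introns of other genes, so they cannot exclude unspliced RNA carried over in general. Small nucleolar RNAs that lie in introns went the other way, with 8 of 12 tested small nucleolar RNAs higher and 0 lower. Within 424 genes with both kinds tested, retained-intron transcripts exceeded protein-coding ones by a median log2 fold change of 1.08 (0.89 to 1.32). This argues against higher expression of the host gene as the whole cause in these genes. The coding side holds only bases of single coding transcripts, not the whole output of the gene. Genes without a tested coding transcript are not covered. Without methylparaben replicate 2 increases were 6.73 times the decreases, against 6.59 with all libraries, and without ethanol replicate 1 they were 10.8 times. A hypothesis left open is that methylparaben changed splicing or the decay of unspliced transcripts. A difference in poly(A) selection or in the carry-over of unspliced RNA might also contribute. Spliced and unspliced reads over the same introns in libraries made without poly(A) selection would tell selection from the other causes, and their decline after a block of transcription would tell splicing from decay.

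Mitochondrial mRNAs fell while mitochondrial rRNAs rose. Scaling by a few abundant genes is excluded only as the cause of the divergence between these classes. The log2 ratio of rRNA to mRNA reads within a library was -2.0 and -1.99 in the ethanol and 0.53 and 0.18 in the methylparaben libraries, a difference of 2.35 (range between libraries 2.17 to 2.53). No scaling can move this ratio, so it does not show which class changed. The fall of the mRNAs and the rise of the rRNAs each depend on the scaling. Less complete poly(A) selection in the methylparaben libraries may have contributed to the rRNA rise. A reason is that 17 RNAs without a poly(A) tail had a median of 1.57 (1.0 to 2.50), with 9 called higher. Abundant RNAs named for this test in advance, such as RMRP and RPPH1, are missing from these 17. Most of the 17 are small nucleolar RNAs that lie in introns, so they are not independent of the retained-intron rise. The ribosomal RNA copies FP236383.3, which had been seen before the test, FP236383.2 and FP671120.3 were at 1.33, 0.91 and 0.59 without a call. In ethanol 1, ethanol 2, methylparaben 1 and methylparaben 2, FP236383.3 was at 159, 57.6, 127 and 422 CPM. FP236383.2 was at 95.3, 31.2, 56.9 and 184 CPM and FP671120.3 at 242, 77.0, 128 and 359 CPM. Each lay between the ethanol libraries in methylparaben replicate 1, so these positive values rest on methylparaben replicate 2. Whether poly(A) selection also lowered the mitochondrial mRNAs was not tested, and a biological decrease of these mRNAs stays untested.

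The methylparaben libraries differed from each other more than the ethanol libraries did, with an SD of log2 replicate 2 over replicate 1 of 0.46 against 0.31 over 2564 genes of at least 50 CPM. GC content and length, a test prompted by short GC-rich genes seen to differ, could account for much of it, since a smooth trend on them explained 0.431 of the variance (95% interval 0.384 to 0.494) against 0.117 for the ethanol libraries. Genes in the top decile of GC content had a median of 0.39 and those in the lowest -0.25, against -0.16 and 0.04 for ethanol. Reads shared between genes and processed pseudogenes cannot be told apart from it, since only 4 short GC-rich genes without shared bases were measured, with a median of 0.170 (-0.004 to 2.92). No biological explanation was tested, since both libraries belong to 1 group.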
